A study of Drosophila melanogaster with 14 samples.

How the data were processed

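The data are read counts per gene from RNA of affinity-isolated embryonic nuclei of Drosophila melanogaster, in 14 libraries. Per the labels, 8 are wild-type libraries of mesodermal or neuronal nuclei at stages 10-13 or 14-17, with 2 replicates each, and 6 are mesodermal libraries of stages 14-17 carrying GFP-tagged Ubx, with 3 replicates each of degraded and control embryos. The labels give total RNA as the molecule and standard Illumina protocols for the libraries, and do not say which strand was read. The deposited files hold raw counts per gene that the authors made with HTSeq, per the submitters' processing notes, which also name FastQC and the builds BDGP6 and dm6. The aligner, all upstream versions, the trimming settings and the gene annotation used are not given in the sources used here. The series also covers Ubx binding and histone marks, which are not analysed here.

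The wild-type tables list 14156 genes and the tables of the degradation libraries 15682, with 13765 gene identifiers in both, so the main fits were run within each set. An alternative fitted all 14 libraries together, and levels of genes near each other on 2L were set side by side across the sets. Assigned counts ranged from 12970816 to 36150646 per wild-type library and from 24314883 to 31033963 per library of the degradation set. In the degradation set the files also give reads not assigned: 42.8 to 48.6% aligned to more than 1 place, 7.4 to 8.9% lay in no gene and 0.8% were ambiguous, which left 42.7 to 48.9% assigned. These lines were kept out of library sizes and tests, and the wild-type tables hold none. The wild-type tables give 0 to most genes that lie wholly inside another gene. Among genes with at least 3000 counts in the degradation libraries, 277 of 310 such nested genes (89.4%) had 0 counts in all wild-type libraries, against 4 of 4678 other genes (0.1%). For this reason elav and other nested genes cannot check the labels of the wild-type libraries. Genes whose span other genes overlap by 40% or more are called uncertain where they are named, because reads could not be told apart by strand.

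Gene symbols and coordinates came from Ensembl annotation release 115 on BDGP6, with a symbol for 98.4% of wild-type genes and 95.7% of genes of the degradation set. Counts were analysed with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3, and tables and plots were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 10549 wild-type genes and 11641 genes of the degradation set. After TMM normalisation, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 5% was run in 1 fit per set, with 4 residual degrees of freedom each. The comparisons were mesoderm against neuronal at each stage, stages 14-17 against 10-13 in each tissue, the difference of those stage changes, and degraded against control. The common biological coefficient of variation was 0.277 in the wild-type set and 0.191 in the degradation set. Levels are CPM, counts scaled to TMM-normalised library sizes.

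The comparisons, tests, 23 gene lists, named gene rule and alternative settings were fixed before the data were examined. The lists cover muscle contractile apparatus, mesoderm and muscle identity factors, heart and visceral mesoderm, myoblast fusion, muscle attachment and tendon, neuronal differentiation and synapse, neuroblast and proneural genes, axon guidance, glia, epidermis and trachea, endoderm and midgut, hemocytes, fat body, germline, salivary gland, Hox genes and cofactors, signalling, Polycomb and trithorax groups, cell cycle and DNA replication, SCF ubiquitin ligase, heat shock and stress, cell death, and the mitochondrial genome. They were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 138 tests, and again with an estimated correlation, under which 0 of the 57 list results past the threshold remained. Counts of list members past the threshold are given over all genes and, for lists past the threshold where they differ, adjusted over the list alone. List symbols that matched no gene in the tables are not analysed here: wupA, ap, hbs, para, VAChT, Dl, btl, dys, dp, PPO1, Nplp2, FASN1, vas, nos, wg, calypso, Mcm3, Orc1, Top2 and slmb.

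Named genes are, per comparison, the 5 higher and 5 lower with the largest change among genes past the threshold with at least 10 CPM in the higher group and no overlap between libraries, or of at least 10 CPM in the highest group for the difference of stage changes. Ubx, abd-A, Abd-B, Antp, twi, Mef2, elav and slmb were to be named always. Per list, up to 2 higher and 2 lower members with the smallest adjusted p were added, or the member with the highest level where none passed, and members of lists that are only counted may be left out. Tissue sets for the degradation comparison are genes past the threshold and at least 2-fold higher in 1 tissue at stages 14-17.

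The tests were tested on simulated data with 200 changed genes. In the design of the degradation set, 13.4, 58.2 and 100% of genes changed 1.5-, 2- and 4-fold were recovered, with 10.9% false among 128 calls. In that of the tissues at stages 14-17, 1.5, 4.5 and 66.7% were recovered, with 2% false among 49 calls. The real comparison of these tissues had 4340 genes past the threshold, which makes the adjusted cut-off less strict. The recovered shares therefore do not carry over to it. The false share of 10.9% in the degradation design, from 1 simulation, was above the 5% set. Alternatives tried were DESeq2's size factors, library totals, a filter at 5 CPM and none, DESeq2 and limma-voom, a test against a 1.5-fold change, fits of fewer or all libraries, a replicate block, tissue sets at 4-fold or from stages 10-13, and each library left out in turn. Leaving out both controls of highest mitochondrial share, the mitochondrial share as a covariate, and leaving out mitochondrial genes were added after seeing the data. Where 1 library is left in a group, that library is assumed to vary like the other groups.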

Results

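RNA was sequenced from nuclei of Drosophila melanogaster embryos isolated by INTACT, a method in which nuclei that carry a tag in 1 tissue are pulled out of an embryo lysate by affinity. In wild-type embryos the tag was expressed under twi for mesodermal nuclei or through elav for neuronal nuclei, at embryonic stages 10-13 and 14-17, with 2 libraries per tissue and stage. A further set held mesodermal nuclei at stages 14-17 from embryos whose Ubx protein was fused to GFP. In 3 of these libraries Mef2 drove Nslmb, a fusion built on part of the F-box protein Slmb that sends GFP-tagged protein to degradation. The 3 control libraries carried the Nslmb transgene without a driver. Counts assigned to genes totalled 12970816 to 17905141 in the wild-type mesoderm libraries and 27924215 to 36150646 in the neuronal libraries. They totalled 24314883 to 31033963 in the controls and 24391565 to 28150883 in the degraded libraries. The labels do not say whether replicates came from separate embryo collections, so all p-values measure only the spread between these samples, which may be technical. All adjusted p-values for genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those for gene lists from limma's camera. Gene levels are in CPM (counts scaled to normalised library size), as mean ± SD. Changes are log2 values ± SE.

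Ubx, a Hox transcription factor of the posterior thorax and abdomen, and its protein's removal are the subject of the study. The Ubx gene (FBgn0003944) lies at 16656623 to 16734426 on the minus strand of chromosome arm 3R (BDGP6), and 12.6% of this span is overlapped by other genes. Ubx mRNA was highest in mesoderm at stages 10-13, at 857 ± 27.7 CPM (n = 2), and stood at 408 ± 57.6 CPM in mesoderm at stages 14-17. Neuronal nuclei held 122 ± 7.02 CPM at stages 10-13 and 113 ± 17.8 CPM at stages 14-17 (n = 2 each). In the degradation set, the 3 controls held 68.9, 60.3 and 71.0 CPM and the 3 degraded libraries 62.7, 79.1 and 89.8 CPM, a log2 difference of 0.21 ± 0.15 that did not pass the test (adjusted p = 0.448, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Nslmb acts on protein, so Ubx mRNA does not check the labels of these libraries. The wild-type and degradation sets were counted in separate tables and normalised apart. Levels of Ubx are therefore not directly comparable between them, and why they were lower in the degradation set was not tested.

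The first comparison asked how mesodermal and neuronal nuclei differed at stages 10-13. Mesodermal nuclei held more RNA of mesoderm regulators, signalling genes and cell cycle genes, while neuronal nuclei held more RNA of synaptic genes, epidermal genes and several contractile genes. These are list results at camera's preset correlation, and none of these lists passed with an estimated correlation (adjusted p from 0.332 to 0.685). The mesoderm determinant twi stood at 404 ± 46.8 CPM in mesoderm and 5.83 ± 1.96 CPM in neuronal nuclei (n = 2 each). It was higher by 6.11 ± 0.34. Mef2, a regulator of muscle differentiation, was higher by 2.65 ± 0.20 (1140 ± 193 against 182 ± 11.2 CPM), and Ubx by 2.82 ± 0.21 (adjusted p = 0.00015, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The synaptic vesicle glutamate transporter gene VGlut differed by -4.01 ± 0.39 and the Na,K-ATPase subunit gene nrv3 by -3.94 ± 0.31, from 9.76 ± 1.79 CPM in mesoderm and 150 ± 12.4 CPM in neuronal nuclei. Because twi directed the tag of the mesoderm libraries, it is tied to the isolation. Whether the tag's transcript carries twi sequence is not given in the sources used here. Other genes overlap 60.8% of the twi span, which makes its value uncertain.

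**Figure D1:**
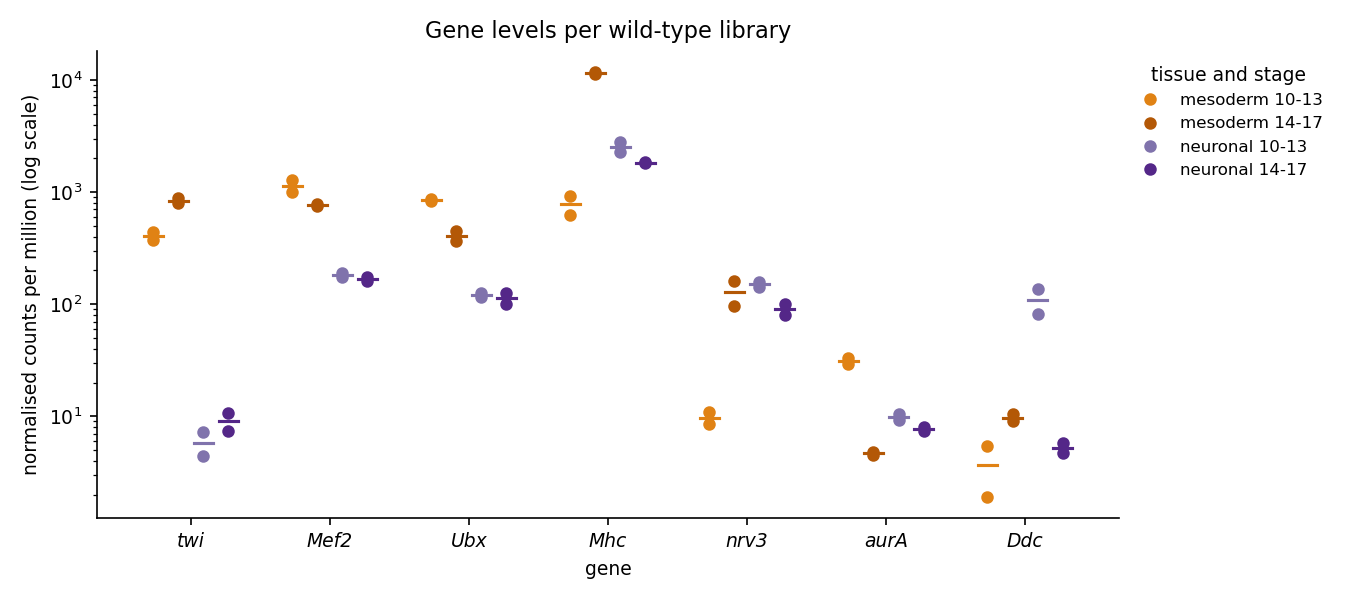
Normalised CPM (log axis) of 7 genes in the 8 wild-type libraries, with a point per library and a bar at the mean of each tissue and stage (n = 2). The mesoderm points of twi, Mef2 and Ubx lie above the neuronal points at both stages, and Mhc stands at 11600 CPM in mesoderm at stages 14-17 against 777 CPM at stages 10-13.

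Among the fixed lists, 19 of 26 tested mesoderm and muscle identity factors were higher in mesoderm at stages 10-13 and 0 lower, with 21 higher when adjusted over the list alone. The median of this list was 1.96 (adjusted p = 2.59e-13; adjusted p = 0.334 with an estimated correlation), and lmd, a regulator of myoblasts, was higher by 4.52 ± 0.26. Of 13 myoblast fusion genes 11 were higher, among them the cell adhesion gene sns (4.2 ± 0.25); the median was 1.14 (adjusted p = 8.04e-07; adjusted p = 0.334 with an estimated correlation). Heart and visceral mesoderm genes were higher in 14 cases and lower in 3 of 18, with org-1 higher by 3.33 ± 0.19 and prc lower, at -2.49 ± 0.50 (adjusted p = 2.05e-05; adjusted p = 0.191 with an estimated correlation). Muscle attachment genes were higher in 9 and lower in 2 of 16 cases (9 and 3 adjusted over the list alone), with the laminin gene wb at 3.04 ± 0.19 (adjusted p = 0.000417; adjusted p = 0.332 with an estimated correlation). The contractile apparatus went the other way, with 3 of 29 members higher and 16 lower (3 and 17 adjusted over the list alone) and a median of -1.33. Its adjusted p was 0.0247 (adjusted p = 0.400 with an estimated correlation), the myosin light chain gene Mlc2 stood at -2.97 ± 0.37, and the calcium release channel gene RyR at 1.52 ± 0.22.

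Of 30 neuronal differentiation and synapse genes, 20 were lower in mesoderm and 2 higher at stages 10-13, the same numbers when adjusted over the list alone (median -1.98, adjusted p = 0.00086; adjusted p = 0.685 with an estimated correlation). The 2 that were higher in mesoderm were the cadherin gene CadN (1.46 ± 0.25) and the zinc finger gene scrt (1.42 ± 0.20). Genes of neural precursors were higher in mesoderm in 15 of 19 cases (16 adjusted over the list alone; median 1.58, adjusted p = 1.63e-07; adjusted p = 0.400 with an estimated correlation). So were 17 of 20 axon guidance genes with 2 lower (adjusted p = 1.13e-07; adjusted p = 0.400 with an estimated correlation). The guidance cue gene NetB was higher by 2.73 ± 0.23 and the receptor gene robo3 lower, at -2.86 ± 0.50. All 4 remaining regulatory lists were higher in mesoderm. Hox genes and cofactors were higher in 7 of 12 cases (adjusted p = 0.000165; adjusted p = 0.334 with an estimated correlation), and signalling genes in 19 of 22 (adjusted p = 3.85e-13; adjusted p = 0.332 with an estimated correlation). Polycomb and trithorax genes were higher in 22 of 28 cases (23 adjusted over the list alone, adjusted p = 2.40e-07; adjusted p = 0.400 with an estimated correlation). The last list was cell cycle and DNA replication genes (18 of 22, 19 adjusted over the list alone, adjusted p = 3.38e-06; adjusted p = 0.485 with an estimated correlation). In these lists the homeobox cofactor gene hth was higher by 3.23 ± 0.32, the receptor genes ptc and N by 3.63 ± 0.27 and 3.23 ± 0.26, and the mitotic phosphatase gene stg by 2.93 ± 0.29.

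Epidermis and tracheal genes were lower in mesoderm in 10 and higher in 3 of 18 cases at stages 10-13 (11 and 5 adjusted over the list alone; adjusted p = 0.0111; adjusted p = 0.641 with an estimated correlation). The chitin deacetylase gene serp stood at -3.37 ± 0.28, and shg, which encodes E-cadherin, at 1.68 ± 0.21. The 4 genes CG3355, CG8543, CG32248 and CG13443 had 0 counts in both mesoderm libraries. They stood at 396 ± 218, 90.3 ± 6.55, 58.7 ± 5.78 and 48.6 ± 17.2 CPM in neuronal nuclei. The cuticle protein gene Cpr47Ec stood at 0.0312 ± 0.0441 against 324 ± 239 CPM. CG32305 showed the opposite, with 227 ± 37.3 CPM in mesoderm and 0.17 ± 0.0697 CPM in neuronal nuclei. So did the receptor-like gene mthl8 (44.5 and 0.0674 CPM), CG45691 (10.1 and 0 CPM), CG15109 (18 and 0.0987 CPM) and CG10764 (97.2 and 0.818 CPM). Heat shock and stress genes were lower in mesoderm in 8 of 16 cases, including GstD1 at -4.87 ± 0.47 (adjusted p = 0.0206; adjusted p = 0.592 with an estimated correlation, and 0.143 without mesoderm replicate 1 of stages 10-13). The lists of glia (6 higher, 6 lower of 14), endoderm and midgut (5 and 7 of 14), hemocytes (6 and 7 of 16), fat body (4 and 4 of 12), germline (1 and 0 of 9), salivary gland (3 and 0 of 8), SCF ubiquitin ligase (1 and 0 of 6), cell death (3 and 3 of 8) and the mitochondrial genome (0 and 3 of 13) did not pass the test, though the last passed without neuronal replicate 1 (adjusted p = 0.0425). In all, 5566 of 10549 tested genes differed, 2451 higher and 3115 lower in mesoderm. Normalising by library totals alone gave 1664 higher and 3707 lower (31% against 44% higher) and moved the median of all genes from -0.08 to -0.33. Of the named genes past the threshold, 72 of 79 kept their calls without each library in turn.

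The second comparison asked how the same tissues differed at stages 14-17. The giant sarcomere protein genes bt and sls were higher in mesoderm by 3.71 ± 0.32 and 3.66 ± 0.29 (15800 ± 1890 against 1210 ± 333 CPM, and 9260 ± 1390 against 734 ± 42.3 CPM, n = 2 each). The mesoderm gene twi was higher by 6.54 ± 0.35, Mef2 by 2.18 ± 0.20 and Ubx by 1.85 ± 0.20 (adjusted p = 0.00125, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Among the other Hox genes, Abd-B was higher by 0.85 ± 0.19 and Antp by 0.84 ± 0.21, while abd-A differed by 0.42 ± 0.16 and did not pass (adjusted p = 0.0692). The Abd-B call was lost without mesoderm replicate 2 (adjusted p = 0.08), and that of Antp without mesoderm replicate 1 or 2 (0.0917 and 0.0984) and with library totals alone (0.136). The gene Antp has 60.3% of its span overlapped by other genes. The neuronal list was not higher in the neuronal libraries: 8 of 30 members were higher in mesoderm and 0 lower, 7 and 0 adjusted over the list alone. Its median was 0.55 (adjusted p = 0.00333; adjusted p = 0.710 with an estimated correlation, and 0.0708 without neuronal replicate 2), with the potassium channel gene Sh at 4.58 ± 0.50 and the RNA-binding protein gene Rbp9 at 2.41 ± 0.21.

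Of 29 contractile genes, 21 were higher in mesoderm at stages 14-17 and 0 lower (22 adjusted over the list alone; median 2.14, adjusted p = 2.75e-15; adjusted p = 0.143 with an estimated correlation). Of 26 identity factors 20 were higher (median 1.59, adjusted p = 7.54e-11; adjusted p = 0.334 with an estimated correlation), and of 16 muscle attachment genes 10 (adjusted p = 3.37e-08; adjusted p = 0.191 with an estimated correlation). Of 18 heart and visceral mesoderm genes 9 were higher (adjusted p = 0.0024; adjusted p = 0.295 with an estimated correlation), and of 13 fusion genes 9 (adjusted p = 0.000381; adjusted p = 0.409 with an estimated correlation). In these 4 lists 0 members were lower. The tendon regulator sr was higher by 3.15 ± 0.24, the integrin gene if by 2.93 ± 0.20 and the adhesion gene kirre by 3.89 ± 0.47. Hemocyte list genes were higher in 10 and lower in 1 of 16 cases (median 1.36, adjusted p = 0.000193; adjusted p = 0.191 with an estimated correlation). The matrix gene Tig stood at 2.46 ± 0.27, and Hml, a hemocyte marker, at -3.00 ± 0.92.

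Axon guidance genes were higher in mesoderm in 15 of 20 cases (16 adjusted over the list alone; adjusted p = 9.84e-08; adjusted p = 0.400 with an estimated correlation). Signalling genes were higher in 14 of 22 (15 adjusted over the list alone; adjusted p = 1.24e-09; adjusted p = 0.397 with an estimated correlation) and Hox genes and cofactors in 8 of 12 (9 adjusted over the list alone; adjusted p = 0.00131; adjusted p = 0.369 with an estimated correlation). The EGF receptor ligand gene vn was higher by 3.43 ± 0.18 and the BMP antagonist gene sog by 3.81 ± 0.22. Epidermis and tracheal genes were higher in 7 and lower in 1 of 18 cases (adjusted p = 0.0265; adjusted p = 0.655 with an estimated correlation, and 0.234 without neuronal replicate 1). Cell cycle genes were lower in mesoderm in 15 and higher in 1 of 22 cases (16 and 1 adjusted over the list alone; median -0.73, adjusted p = 0.000349; adjusted p = 0.555 with an estimated correlation). The mitotic kinase gene Cdk1 stood at -1.68 ± 0.20, and the member that was higher was CycE (1.51 ± 0.25). Genes of the mitochondrial genome were lower in 8 of 13 cases (12 adjusted over the list alone; median -1.96, adjusted p = 0.00274; adjusted p = 0.685 with an estimated correlation, and 0.0528 without neuronal replicate 2). They made up 1.0 and 1.51% of counts in these mesoderm libraries and 3.40 and 6.94% in the neuronal ones.

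Among genes of at least 10 CPM in the higher group and without overlap between libraries, those with the most extreme difference towards the neuronal libraries at stages 14-17 were at or near 0 in mesoderm and varied widely between the neuronal libraries. The serine protease gene Jon99Fi stood at 18.6 and 590 CPM in the neuronal libraries, Jon65Ai at 6.19 and 238 CPM, the urate oxidase gene Uro at 2.31 and 50.7 CPM, Alp7 at 11.4 and 352 CPM and CG10081 at 4.03 and 26.9 CPM. By the same rule, the highest in mesoderm relative to neuronal nuclei were CG32305 (9.68 ± 0.40), CG10764 (7.13 ± 0.39), mthl8 (7.05 ± 0.41), twi and CG3984 (6.06 ± 0.46), whose span other genes overlap in full. Lists of neuroblast genes (7 higher, 3 lower of 19), glia (4 and 2 of 14), endoderm (4 and 8 of 14), fat body (3 and 0 of 12), germline (1 and 1 of 9), salivary gland (3 and 0 of 8), Polycomb and trithorax groups (10 and 4 of 28), SCF ligase (0 and 3 of 6), heat shock (1 and 6 of 16) and cell death (1 and 3 of 8) did not pass. Salivary gland passed without mesoderm replicate 1 (adjusted p = 0.017), endoderm without neuronal replicate 1 or 2 (6.11e-07 and 0.0251) and heat shock without neuronal replicate 2 (0.0321). In all, 4340 genes differed, 2004 higher and 2336 lower in mesoderm. Normalising by library totals alone gave 1375 higher and 3554 lower (27.9% against 46.2% higher). The larger side changed with the setting. In mesoderm 960 were higher and 368 lower without mesoderm replicate 1 (1328 in all), and 1168 and 715 without mesoderm replicate 2 (1883). They were 1491 and 1319 in a fit of only these 4 libraries (2810), and 2040 and 1808 with limma-voom. Of the named genes past the threshold, 46 of 69 kept their calls without each library in turn.

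The change with stage was measured next, first in mesoderm. Of 29 contractile genes 26 rose between stages 10-13 and 14-17, among them the muscle myosin heavy chain gene Mhc, from 777 ± 210 to 11600 ± 399 CPM (n = 2 each), a log2 change of 3.90 ± 0.30. Osi16, of a family of secreted or membrane proteins encoded side by side, rose by 6.91 ± 0.74 and its relatives Osi18, Osi9 and Osi19 by 5.68 ± 0.70, 5.32 ± 0.74 and 5.30 ± 0.70. The gene tpr rose by 6.06 ± 0.68. These 5 rises were the greatest among genes of at least 10 CPM in the higher group and without overlap between libraries. The greatest falls by that rule were those of CG10035 (-6.82 ± 0.81), the Wnt gene wntD (-6.63 ± 0.83), CG45691 (-6.26 ± 0.65), BobA (-6.00 ± 0.64) and CG4440 (-5.94 ± 0.49). The kinase gene aurA, which acts in mitosis, fell by 2.74 ± 0.23 on the log2 scale and the proneural gene ato fell by 5.65 ± 0.42. Ubx fell by 1.07 ± 0.20 (adjusted p = 0.00387, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Abd-B fell by 0.79 ± 0.19 and Mef2 fell by 0.57 ± 0.19, while twi rose by 1.05 ± 0.28. Neither abd-A (-0.45 ± 0.16, adjusted p = 0.051) nor Antp (-0.49 ± 0.21, adjusted p = 0.0886) passed, though abd-A did with library totals alone (adjusted p = 0.0157). The twi call was lost without each library in turn (adjusted p from 0.0688 to 0.124). That of Mef2 was lost without replicate 1 of stages 10-13 (0.219), replicate 1 or 2 of stages 14-17 (0.128 and 0.145) and with DESeq2's size factors (0.0518), and that of Abd-B without replicate 1 of stages 14-17 (0.0785).

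In mesoderm, 26 of 29 contractile genes rose and 0 fell with stage (27 adjusted over the list alone; median 2.66, adjusted p = 1.36e-15; adjusted p = 0.143 with an estimated correlation), among them the troponin C gene TpnC73F (3.09 ± 0.22). Neuronal differentiation and synapse genes rose in 24 and fell in 1 of 30 cases (25 and 1 adjusted over the list alone; median 2.43, adjusted p = 6.58e-09; adjusted p = 0.555 with an estimated correlation). In this list nrv3 rose by 3.73 ± 0.31, to 130 ± 46.0 CPM, Rbp9 rose by 2.38 ± 0.21, and scrt fell by 0.76 ± 0.20. Epidermis and tracheal genes rose in 11 and fell in 1 of 18 cases (11 and 2 adjusted over the list alone; median 1.48, adjusted p = 0.00131; adjusted p = 0.555 with an estimated correlation), with the chitin-related gene knk at 2.41 ± 0.20 and the actin bundling gene f at 2.99 ± 0.26. Hemocyte list genes rose in 9 and fell in 2 of 16 cases (adjusted p = 0.000165; adjusted p = 0.191 with an estimated correlation), including the collagen genes Col4a1 (3.30 ± 0.21) and vkg (3.08 ± 0.20), which fat body cells also express. Muscle attachment genes rose in 7 of 16 cases (adjusted p = 0.0295; adjusted p = 0.469 with an estimated correlation), with sr at 2.39 ± 0.23. That call was lost without replicate 1 of stages 10-13 (adjusted p = 0.0874) and without replicate 2 of stages 14-17 (0.0765).

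All 22 tested cell cycle and DNA replication genes fell with stage in mesoderm (median -2.07, adjusted p = 1.25e-18; adjusted p = 0.3 with an estimated correlation), with 22 also when adjusted over the list alone. The checkpoint kinase gene BubR1 fell by 2.80 ± 0.22. Neuroblast and proneural genes fell in 14 of 19 cases (16 fell and 1 rose adjusted over the list alone; median -1.24, adjusted p = 8.56e-07; adjusted p = 0.409 with an estimated correlation). Polycomb and trithorax genes fell in 20 of 28 cases (22 adjusted over the list alone; median -0.78, adjusted p = 3.06e-05; adjusted p = 0.530 with an estimated correlation). Signalling genes fell in 11 and rose in 2 of 22 cases (adjusted p = 0.00767; adjusted p = 0.601 with an estimated correlation). In the neuroblast and proneural list, sca fell by 4.11 ± 0.21. The chromatin remodeller gene brm fell by 1.46 ± 0.19 and the receptor gene N by 2.25 ± 0.25. Of the lists that did not pass, identity factors (3 rose, 8 fell of 26) included lmd, which fell by 2.66 ± 0.24, and the homeobox gene Six4, which fell by 3.07 ± 0.26. The others were heart and visceral mesoderm (4 and 8 of 18), fusion (0 and 4 of 13), axon guidance (3 and 6 of 20), glia (3 and 2 of 14), endoderm (0 and 2 of 14), fat body (2 and 0 of 12), germline (2 and 5 of 9), salivary gland (0 and 3 of 8), Hox genes (2 and 2 of 12), SCF ligase (0 and 2 of 6), heat shock (6 and 0 of 16), cell death (2 and 2 of 8) and the mitochondrial genome (0 and 0 of 13). Fusion and heat shock genes passed without replicate 2 of stages 10-13 (adjusted p = 0.0393 and 0.00432), and salivary gland genes without replicate 1 of stages 10-13 (0.0436) or replicate 2 of stages 14-17 (0.0331). In all, 5027 of 10549 genes changed, 2629 upwards and 2398 downwards, against 2310 and 2918 with library totals alone and 2348 and 2381 with the stricter filter. The count was 2862 without replicate 1 of stages 14-17, 3334 without replicate 2 of stages 10-13 and 3347 against a 1.5-fold change, and 54 of 75 named genes past the threshold kept their calls without each library in turn.

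The change between the same stages was then measured in neuronal nuclei. Ddc, which encodes the dopa decarboxylase of cuticle hardening and dopamine synthesis, fell by 4.38 ± 0.50 on the log2 scale, from 109 ± 39.1 to 5.23 ± 0.781 CPM (n = 2 each), and CG14324 fell by 7.53 ± 0.35, from 113 ± 13.7 to 0.6 ± 0.14 CPM. The zinc transporter gene ZnT35C rose by 3.47 ± 0.34, from 25.5 ± 7.84 to 282 ± 97.9 CPM. CG30154, CG34284, tpr and apn rose by 3.90 ± 0.52, 3.51 ± 0.48, 3.38 ± 0.55 and 3.31 ± 0.53. CG7377, CG14851 and CG14326 fell from 13.4, 12 and 172 CPM to 0.0269, 0.0302 and 1.12 CPM, as did CG13040, from 124 to 0.701 CPM, with 41.9% of its span overlapped by other genes. Ubx did not pass (-0.10 ± 0.19, adjusted p = 0.74, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), nor did twi, Mef2, abd-A, Abd-B or Antp, of which Antp passed without replicate 2 of stages 14-17 (adjusted p = 0.0386). Of 30 neuronal differentiation and synapse genes, 0 rose and 1 fell, the GABA receptor gene Rdl (-2.07 ± 0.48; median of the list -0.28). The count was 0 for both directions when adjusted over the list alone, and the list did not pass (adjusted p = 0.453), except without replicate 1 of stages 14-17 (median -0.77, adjusted p = 0.00907).

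Epidermis and tracheal genes fell in 9 and rose in 1 of 18 cases with stage in neuronal nuclei (10 and 1 adjusted over the list alone; median -0.73, adjusted p = 0.0194; adjusted p = 0.641 with an estimated correlation), with Ddc in this list and m, a zona pellucida domain gene, as the one that rose (1.15 ± 0.22). Salivary gland genes fell in 4 of 8 cases (5 adjusted over the list alone; adjusted p = 0.0225; adjusted p = 0.601 with an estimated correlation), among them sage (-1.94 ± 0.37). Muscle attachment genes rose in 5 and fell in 1 of 16 cases (5 and 2 adjusted over the list alone; adjusted p = 0.0194; adjusted p = 0.435 with an estimated correlation), with the laminin gene LanB2 at 1.21 ± 0.18. Hemocyte list genes rose in 5 of 16 cases (6 adjusted over the list alone; adjusted p = 0.0327; adjusted p = 0.369 with an estimated correlation), with the matrix gene SPARC at 1.07 ± 0.21. The mitochondrial genome list had a median of 0.90 with 0 of 13 members past the threshold, also when adjusted over the list alone (adjusted p = 0.0234; adjusted p = 0.744 with an estimated correlation). Each of these 5 calls was lost without some library: epidermis without replicate 1 of stages 14-17 (adjusted p = 0.382), and salivary gland without replicate 2 of stages 14-17 (adjusted p = 0.154). The attachment call was lost without replicate 2 of stages 10-13 (adjusted p = 0.0592) or replicate 1 of stages 14-17 (0.0938). The hemocyte call was lost without replicate 2 of stages 10-13 (adjusted p = 0.058) or either replicate of stages 14-17 (0.193 and 0.326), and that of the mitochondrial genome without replicate 1 of stages 10-13 (0.367) or replicate 2 of stages 14-17 (0.439).

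The remaining lists did not pass in neuronal nuclei. Contractile genes fell in 7 of 29 cases and rose in 0, with the nuclear positioning gene Msp300 at -1.87 ± 0.27. The others were identity factors (1 rose and 0 fell of 26), heart and visceral mesoderm (4 and 1 of 18), fusion (1 and 1 of 13), neuroblast genes (2 and 2 of 19), axon guidance (0 and 0 of 20), glia (0 and 2 of 14), endoderm (3 and 0 of 14), fat body (1 and 3 of 12), germline (2 and 3 of 9) and Hox genes (1 and 0 of 12). To these add signalling (0 and 3 of 22), Polycomb and trithorax groups (1 and 1 of 28), cell cycle (1 and 1 of 22), SCF ligase (2 and 0 of 6), heat shock (2 and 3 of 16) and cell death (1 and 0 of 8). Identity factors passed without replicate 1 of stages 10-13 (adjusted p = 0.0206) or replicate 2 of stages 14-17 (0.00129), and endoderm without replicate 1 of stages 14-17 (2.99e-05). In all, 2154 genes changed, 893 upwards and 1261 downwards, against 1355 and 1334 with DESeq2 and 673 and 1411 with library totals alone. Of the named genes past the threshold, 14 of 58 kept their calls without each library in turn. The number of genes that changed was 386 without replicate 1 and 1084 without replicate 2 of stages 10-13, 4231 without replicate 1 of stages 14-17, 765 in a fit of only these 4 libraries and 878 against a 1.5-fold change.

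**Figure D2:**
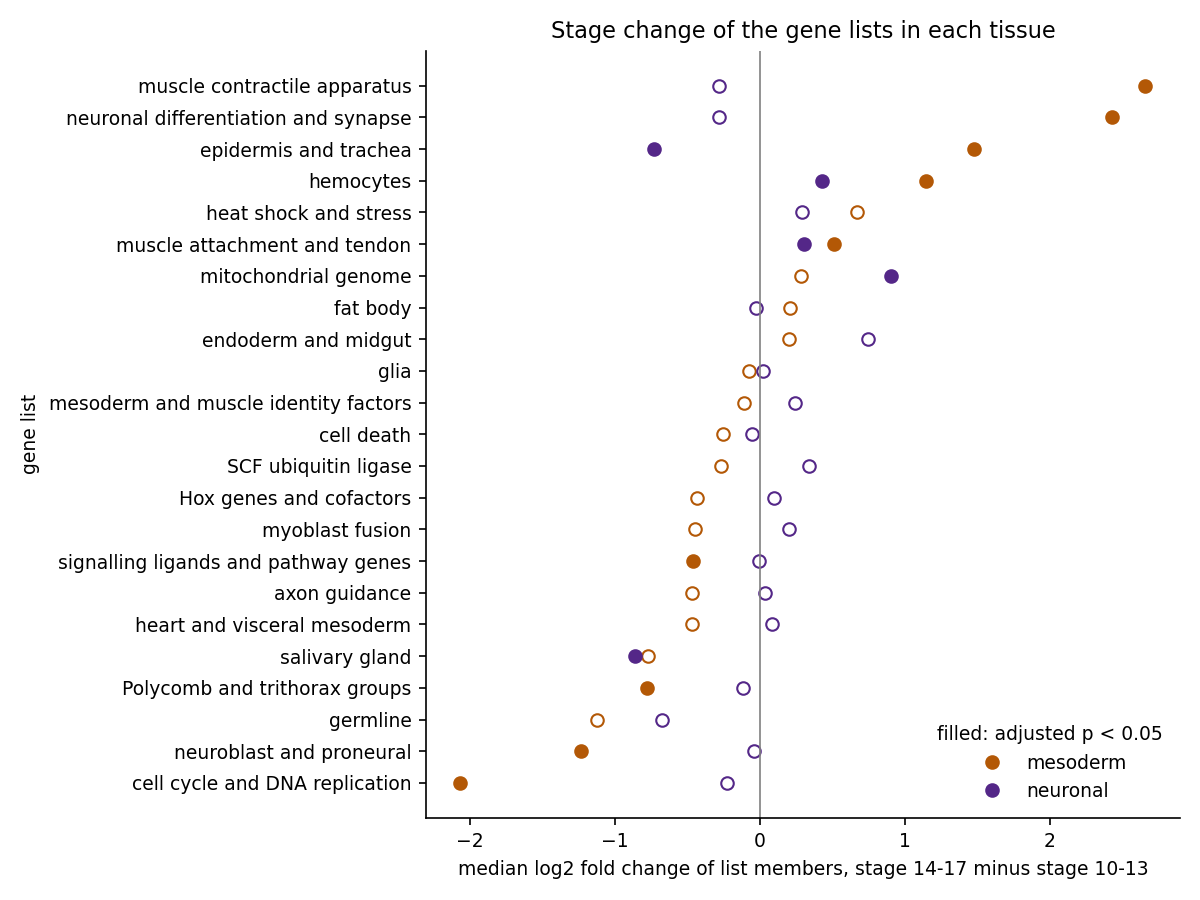
Median log2 fold change of the tested members of each of the 23 gene lists between stages 10-13 and 14-17 (x axis; positive is higher at stages 14-17), in mesoderm (orange) and neuronal nuclei (purple); filled points have an adjusted p under 0.05 from camera with its preset correlation. The contractile list stands at 2.66 in mesoderm and -0.28 in neuronal nuclei, and the cell cycle list at -2.07 in mesoderm.

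Whether the stage change differed between the tissues was tested as the difference itself, the mesoderm change minus the neuronal change. Mhc differed by 4.36 ± 0.39, Msp300 by 4.39 ± 0.39 and nrv3 by 4.47 ± 0.41, each with a more positive change in mesoderm. Ubx differed by -0.97 ± 0.27 (adjusted p = 0.0299, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Abd-B by -1.01 ± 0.27 and abd-A by -0.78 ± 0.23, while Antp (-0.79 ± 0.29, adjusted p = 0.0694), twi (0.43 ± 0.39) and Mef2 (-0.46 ± 0.27) did not pass. The calls of Ubx, Abd-B and abd-A each held in 3 of the 8 fits with a library left out. They were lost without mesoderm replicates 1 and 2 of stages 10-13 (Ubx 0.0868 and 0.0716, Abd-B 0.0571 and 0.0576, abd-A 0.0663 and 0.081), mesoderm replicate 1 of stages 14-17 (0.117, 0.0713 and 0.0899) and neuronal replicate 2 of stages 10-13 (0.0512, 0.0534 and 0.0594). Ubx and Abd-B were also lost without neuronal replicate 1 of stages 10-13 (0.0703 and 0.0559) and abd-A without mesoderm replicate 2 of stages 14-17 (0.0611), while Antp passed without neuronal replicate 2 of stages 14-17 (0.00482) and with DESeq2 (0.0456). The cell cycle inhibitor gene dap differed by -2.53 ± 0.25 and Cdk1 by -2.33 ± 0.28. In the epidermis list, f differed by 3.65 ± 0.36 and serp by 3.39 ± 0.38. Among genes of at least 10 CPM in the highest group, the most negative differences were those of CG31373 (-5.37 ± 0.92), BobA (-5.22 ± 0.78), CG13793 (-4.91 ± 0.67), wntD (-4.77 ± 1.03) and CG15109 (-4.69 ± 0.84). The most positive were those of CG3355, CG32248, TwdlJ, CG8543 and CG13040, which had no more than 0.0312 CPM in mesoderm at stages 10-13.

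By list, 26 of 29 contractile genes had a more positive change in mesoderm, 24 of 30 neuronal genes with 1 more negative (25 and 1 adjusted over the list alone), and 11 of 18 epidermis genes (11 and 1 adjusted over the list alone). The neuronal list had adjusted p = 3.10e-08 (adjusted p = 0.555 with an estimated correlation) and the epidermis list adjusted p = 2.43e-05 (adjusted p = 0.469 with an estimated correlation). The contractile list had adjusted p = 1.36e-15 (adjusted p = 0.143 with an estimated correlation). The change was more negative in mesoderm for 20 of 22 cell cycle genes (21 adjusted over the list alone; adjusted p = 1.66e-12; adjusted p = 0.348 with an estimated correlation). It was also more negative for 12 of 19 neuroblast genes (adjusted p = 4.68e-05; adjusted p = 0.512 with an estimated correlation) and 12 of 28 Polycomb and trithorax genes (adjusted p = 0.000581; adjusted p = 0.555 with an estimated correlation). The same direction held for 8 of 26 identity factors (adjusted p = 0.0379; adjusted p = 0.685 with an estimated correlation) and for 7 of 22 signalling genes with 3 more positive (10 and 3 adjusted over the list alone; adjusted p = 0.0318; adjusted p = 0.676 with an estimated correlation). The identity call was lost without neuronal replicate 2 of stages 10-13 (adjusted p = 0.0607), mesoderm replicate 1 (0.0517) or neuronal replicate 1 of stages 14-17 (0.401), and the signalling call without these 2 neuronal libraries (0.0598 and 0.0502). The other 15 lists did not pass. Of these, 3 passed when a library was left out: fusion without mesoderm replicate 2 (adjusted p = 0.0254) or neuronal replicate 1 of stages 10-13 (0.0192), or without mesoderm replicate 1 (0.0372) or neuronal replicate 2 of stages 14-17 (0.0475). Hemocytes passed without neuronal replicate 1 of stages 10-13 (0.045), mesoderm replicate 1 (0.041) or neuronal replicate 2 of stages 14-17 (0.0496). The mitochondrial genome passed without neuronal replicate 2 of stages 10-13 (0.00385), mesoderm replicate 1 (0.0339) or neuronal replicate 1 of stages 14-17 (0.0381). In all, 3730 genes differed, 2175 more positive and 1555 more negative in mesoderm. The count was 2000 without mesoderm replicate 1 of stages 14-17, and 2427 and 2464 without mesoderm replicates 1 and 2 of stages 10-13. Of the named genes past the threshold, 46 of 67 kept their calls without each library in turn.

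The last comparison set mesodermal nuclei at stages 14-17 in which Mef2 drove Nslmb against controls without a driver. The driver, the expressed Nslmb and the degradation of Ubx change together between these groups. Their effects cannot be told apart here, and RNA counts give no measure of Ubx protein. The words "after degradation" below name this contrast. TwdlJ, of the Tweedle cuticle proteins, rose from 0.529 ± 0.0929 to 15.8 ± 4.78 CPM (n = 3 each; 4.88 ± 0.30), and Vm26Aa, a vitelline membrane protein gene, from 0.653 ± 0.323 to 16.5 ± 1.03 CPM (4.62 ± 0.30). CG32305 rose from 0.834 ± 0.458 to 14.0 ± 5.0 CPM (4.10 ± 0.40) and rha from 2.08 ± 0.158 to 13.4 ± 1.34 CPM (2.69 ± 0.17). In the epidermis and trachea list 9 of 18 genes rose, by smaller folds, such as the POU-domain gene vvl (1.08 ± 0.13) and serp (1.26 ± 0.15), and 10 of 15 transcripts of the mitochondrial genome fell, for example mt:CoI at -2.01 ± 0.43. Neither list passed with an estimated correlation (adjusted p = 0.191 and 0.400), the counts fell to 0 without control replicate 2, where the medians stayed at 0.815 and -1.93, and mt:CoI kept its call only without control replicate 3 among the 6 fits with a library left out. Among contractile, neuronal and Hox genes, bt stood at -0.12 ± 0.17 and elav at -0.04 ± 0.12 (146 and 142 CPM). The Hox gene abd-A stood at -0.05 ± 0.13, Abd-B at 0.16 ± 0.13, Antp at -0.12 ± 0.13, Mef2 at 0.25 ± 0.12 and twi at 0.45 ± 0.15. These 7 did not pass (adjusted p from 0.116 to 0.865, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), though twi did without control replicate 3 (adjusted p = 0.0188). The neuronal gene elav was thus detected in both groups of these mesodermal isolates. Where this RNA came from was not tested, and the value is uncertain because elav lies inside another gene.

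Among genes of at least 10 CPM in the higher group and without overlap between libraries, the 5 with the greatest rise were TwdlJ (FBgn0039440; 3R 26629918 to 26630825), Vm26Aa (FBgn0003979; 2L 5959596 to 5960340), CG32305 (3L 2248635 to 2252729), rha (3R 25340252 to 25344838) and psd (2L 5963087 to 5964951), the last at 5.67 ± 3.59 and 30.9 ± 0.595 CPM (2.45 ± 0.48, adjusted p = 0.0308). In wild-type nuclei TwdlJ stood at 134 ± 10.4 CPM in neuronal nuclei at stages 10-13 and at 0.542 ± 0.131 CPM in mesoderm at stages 14-17, and CG32305 at 28.7 ± 4.25 CPM in that mesoderm. The 5 with the greatest fall by the same rule varied widely between controls. The peritrophic matrix gene Peritrophin-15a stood at 2.17, 28.6 and 9.86 CPM in the controls and from 0.445 to 0.568 CPM in the degraded libraries (-4.68 ± 0.88). The metallothionein gene MtnA stood at 292, 192 and 79.7 CPM against 30.3 to 51.4 CPM (-2.10 ± 0.42), the midgut protease gene betaTry at -3.35 ± 0.76, CG10513 at -3.14 ± 0.64 and CG6726 at -2.18 ± 0.46, whose span other genes overlap in full.

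**Figure D3:**
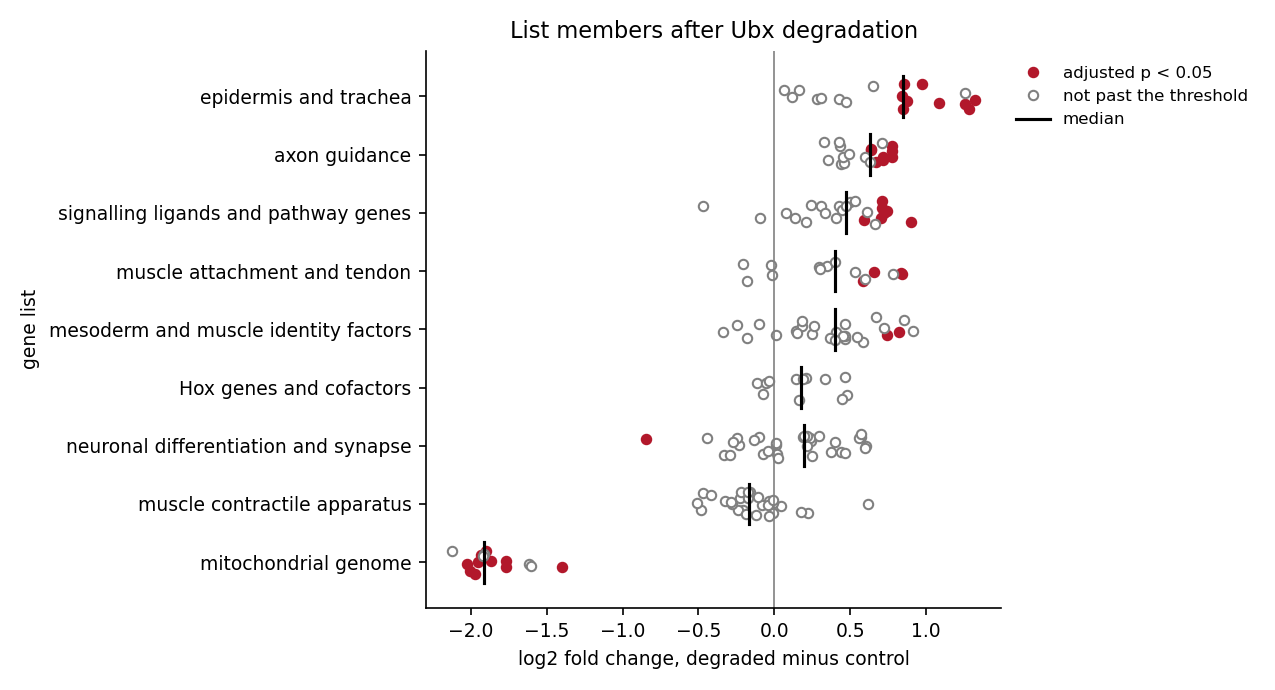
Log2 fold change (degraded minus control, n = 3 each) of each tested member of 9 gene lists, with red points for genes with an adjusted p under 0.05, open points for the others and a black bar at the median of each list. The medians run from 0.84 for epidermis and trachea to -1.91 for the mitochondrial genome.

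Epidermis and tracheal genes rose in 9 of 18 cases after degradation, with 13 adjusted over the list alone and 0 lower (median 0.84, adjusted p = 1.44e-14; adjusted p = 0.191 with an estimated correlation). Axon guidance genes rose in 8 of 19 cases (19 adjusted over the list alone; median 0.63, adjusted p = 2.27e-12; adjusted p = 0.191 with an estimated correlation), among them the netrin receptor gene fra (0.64 ± 0.12) and Nrt (0.64 ± 0.12). Signalling genes rose in 7 of 23 cases (16 higher and 1 lower adjusted over the list alone; median 0.47, adjusted p = 9.30e-09; adjusted p = 0.334 with an estimated correlation), led by the BMP receptor gene tkv (0.90 ± 0.11) and the Wnt receptor gene fz2 (0.71 ± 0.12). Muscle attachment genes rose in 4 of 15 cases (10 adjusted over the list alone; median 0.40, adjusted p = 0.000173; adjusted p = 0.400 with an estimated correlation), including the tendon gene Tsp (0.83 ± 0.16) and Lrt (0.84 ± 0.15). Identity factors rose in 2 of 26 cases (3 adjusted over the list alone; median 0.40, adjusted p = 0.000358; adjusted p = 0.592 with an estimated correlation), the FGF receptor gene htl (0.82 ± 0.17) and the Iroquois gene caup (0.74 ± 0.14). The medians moved little with a library left out, from 0.743 to 0.895 for epidermis, 0.533 to 0.673 for axon guidance, 0.448 to 0.493 for signalling, 0.354 to 0.517 for attachment and 0.328 to 0.494 for identity, while the numbers of genes past the threshold depended on single libraries. Without control replicates 1, 2 and 3 and degraded replicates 1, 2 and 3, the genes past the threshold were 6, 0, 11, 9, 3 and 5 for epidermis, 0, 0, 14, 3, 0 and 1 for axon guidance, and 2, 0, 13, 3, 1 and 2 for signalling. They were 1, 0, 8, 2, 0 and 0 for attachment and 0, 0, 8, 2, 0 and 0 for identity. Transcripts of the mitochondrial genome made up 5.95, 3.57 and 1.39% of counts in the 3 controls and 1.06, 0.96 and 0.87% in the degraded libraries. Without control replicates 1 and 2, where this share is highest, the medians were 0.63 for epidermis (adjusted p = 8.11e-08), 0.42 for axon guidance (adjusted p = 1.85e-06) and 0.40 for signalling (adjusted p = 0.000187). The attachment and identity calls were lost without these 2 libraries (0.19 and 0.17, adjusted p = 0.0813 and 0.104). With the mitochondrial share as a covariate the medians were 0.49 for epidermis (adjusted p = 3.34e-05), 0.39 for axon guidance (adjusted p = 0.000132) and 0.41 for signalling (adjusted p = 0.00163), and attachment and identity were lost (0.09 each, adjusted p = 0.332 and 0.581).

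Mitochondrial genome transcripts fell in 10 of 15 cases (15 adjusted over the list alone; median -1.91, adjusted p = 7.63e-14; adjusted p = 0.400 with an estimated correlation). The number was 15 without control replicate 3 and 0 without any other library of the set, with medians from -2.3 to -1.32. Without control replicates 1 and 2 the median was -0.52 (adjusted p = 3.25e-09). Neuroblast genes had a median of 0.24 with 0 of 22 past the threshold (adjusted p = 0.015; adjusted p = 0.555 with an estimated correlation, and 0.0904 without degraded replicate 3). Its median was 0.33 (adjusted p = 0.00345) without control replicates 1 and 2 and 0.37 (adjusted p = 0.0184) with the covariate. The contractile list had a median of -0.17 with 0 of 28 past the threshold (adjusted p = 0.041; adjusted p = 0.685 with an estimated correlation). This last call was lost without control replicate 3 (adjusted p = 0.425), degraded replicate 1 (0.128) or degraded replicate 3 (0.103), and with the size factors of DESeq2 (0.0584). In the added settings the median was -0.37 (adjusted p = 1.17e-06) without control replicates 1 and 2 and -0.35 (adjusted p = 5.3e-08) with the covariate. For these 2 lists of 0 called genes the number was also 0 when adjusted over the list alone.

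Lists that did not pass after degradation still held single genes that did. In the heart and visceral mesoderm list (2 of 18; 4 adjusted over the list alone) the basement membrane gene Ndg rose from 1600 ± 399 to 4310 ± 1020 CPM (1.43 ± 0.23) and the adhesion gene Fas3 rose by 0.91 ± 0.16. In the neuronal list the GABA synthesis gene Gad1 fell by 0.84 ± 0.13, and the other 31 of 32 members did not pass. The hemocyte list (16 tested) had 1 rise, Tig (0.74 ± 0.14), and 1 fall, Hml (-1.43 ± 0.28). The endoderm list (15 tested; 4 higher and 1 lower adjusted over the list alone) had fkh at 0.73 ± 0.12 beside betaTry. The fat body list (9 tested) had Lsp2 at 2.28 ± 0.31, from 0.556 ± 0.191 to 2.67 ± 0.483 CPM, with 84.6% of its span overlapped by other genes. The Polycomb and trithorax list (28 tested) had ash1 at 0.61 ± 0.12 and the cell cycle list (22 tested; median -0.05) CycE at 0.59 ± 0.13. In the added settings the cell cycle list passed, at 0.40 (adjusted p = 1.18e-05) without control replicates 1 and 2 and at 0.59 (adjusted p = 1.11e-07) with the covariate. The Polycomb and trithorax list passed without these 2 controls (0.0491) or degraded replicate 1 (0.0408), the heart list without control replicate 3 (0.0382) or degraded replicate 1 (0.0457), and heat shock without control replicate 2 (0.0198). Lists with 0 members past the threshold over all genes were Hox genes and cofactors (12 tested, median 0.17), fusion genes (14), glia (16), germline (10), salivary gland (8), SCF ligase (6), heat shock (15; 4 higher and 1 lower adjusted over the list alone) and cell death (9).

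Genes called higher in either tissue at stages 14-17 by at least 2-fold were then taken as sets, from the wild-type libraries, to ask whether genes of the other lineage moved when Ubx was degraded. The set higher in neuronal nuclei had 3 of 1444 tested genes higher and 43 lower after degradation (median -0.35, adjusted p = 1.08e-15; adjusted p = 0.339 with an estimated correlation). The set higher in mesoderm had 119 higher and 8 lower of 1450 (median 0.12, adjusted p = 3.20e-07; adjusted p = 0.339 with an estimated correlation). The neuronal set held 74 cytoplasmic ribosomal protein genes, 35 mitochondrial ribosomal protein genes, 8 genes of the mitochondrial genome and 0 members of the neuronal list, of which the mesoderm set held 7. With the first 3 kinds, the Jon protease genes and the endoderm and midgut list removed, 1309 genes of the neuronal set were left, with a median of -0.32. Sets taken at stages 10-13 gave -0.04 for the neuronal set (adjusted p = 0.747, with camera's direction reversed), while the mesoderm set kept its direction and call. Without control replicates 1 and 2, a choice made after seeing the data, the medians were 7e-06 and -0.04 (adjusted p = 0.48 and 0.47). With the mitochondrial share as a covariate, also added later, both sets passed in the opposite direction, at 0.18 for the neuronal set (adjusted p = 0.0369) and -0.06 for the mesoderm set (adjusted p = 0.00134).

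In all, 557 of 11641 tested genes changed after degradation, 416 upwards and 141 downwards, against 743 and 495 (1238 in all) with the replicate block and 706 and 496 (1202) with DESeq2. The libraries of the groups did not overlap for 3241 genes, where chance alone gives 10%. The count moved with single libraries: 238, 34 and 1645 (753 upwards and 892 downwards) without control replicates 1, 2 and 3, and 316, 64 and 167 without degraded replicates 1, 2 and 3. Of the 31 named genes past the threshold, 4 kept their calls without each library in turn, TwdlJ, Vm26Aa, CG32305 and rha. With the 2 controls of highest mitochondrial share left out, 18 genes passed, and 5 of the 31 named genes did: TwdlJ, Vm26Aa, rha, psd and Peritrophin-15a. With the mitochondrial share as a covariate edgeR called 0 genes, 1947 had an unadjusted p under 0.05, and limma-voom also called 0. In that fit TwdlJ stood at 4.92 ± 0.59 and Vm26Aa at 4.59 ± 0.59 (adjusted p = 0.055 each). Both settings were added after seeing the data.

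Genes raised at least 4-fold lay together on chromosome arm 2L, between 5922876 and 5964951 of BDGP6, and these genes other than Vm26Aa and psd were chosen after their values were seen. The 9 raised genes there were CG9016, asRNA:CR43926, dsf, CG13999, CG13998, Vm26Ab, Vm26Ac, Vm26Aa and psd. The nuclear receptor gene dsf rose from 0.153 to 5.29 CPM (5.04 ± 0.31), Vm26Ac from 0.0898 to 4.25 CPM (5.57 ± 0.39) and CG13999 from 0.736 to 7.63 CPM (3.37 ± 0.19). The antisense RNA gene asRNA:CR43926 overlaps dsf, and without stated strand use its value (5.76 ± 0.73) is uncertain. The neighbours bchs (0.02 ± 0.14), Gpdh1 (-0.33 ± 0.16) and CG9044 (0.07 ± 0.14) between or beside them did not pass. In wild-type mesoderm at stages 14-17, counted in separate tables, dsf stood at 5.79 CPM, Vm26Aa at 12.6 CPM and psd at 40.0 CPM. Unlike other levels, these 3 were scaled to library totals without TMM.

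**Figure D4:**
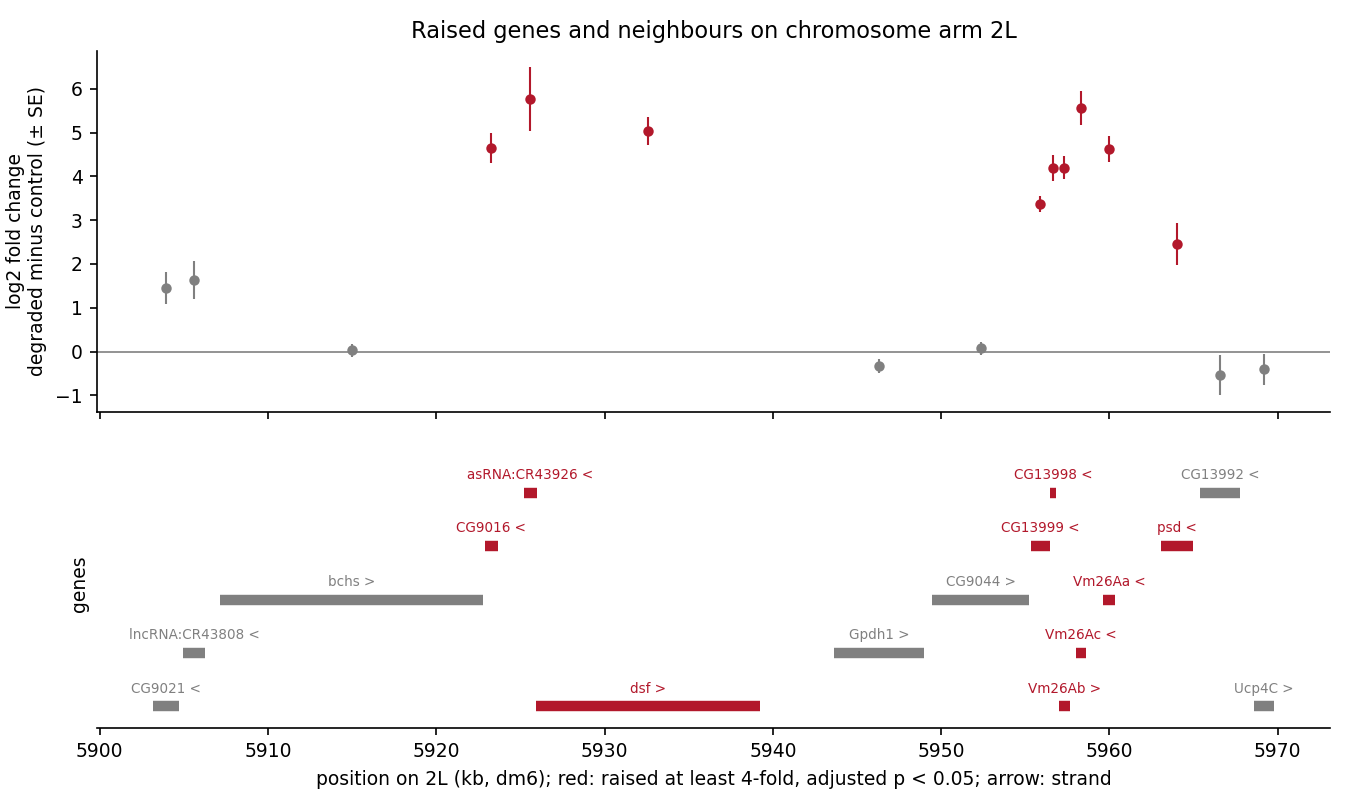
Raised genes and their neighbours on 2L (x axis, position in kb): the upper panel gives the log2 fold change, degraded minus control, with its SE (n = 3 each), and the lower panel each gene's span with an arrow for its strand. The 9 genes in red rose at least 4-fold with an adjusted p under 0.05, and Gpdh1 and CG9044 between them stand at -0.33 and 0.07.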

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

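The test of the difference between stage changes was planned before the data were examined, and both explanations weighed here were chosen after the result was seen. The stage change differed between mesodermal and neuronal nuclei, by a test of the difference itself, for 3730 genes and, with camera's preset correlation, 8 gene lists, of which 0 passed with an estimated correlation (adjusted p from 0.143 to 0.685). The number of genes was 2000 without mesoderm replicate 1 of stages 14-17, and 2427 and 2464 without mesoderm replicates 1 and 2 of stages 10-13. Of the lists, identity factors were lost without neuronal replicate 2 of stages 10-13 (adjusted p = 0.0607), mesoderm replicate 1 (0.0517) or neuronal replicate 1 of stages 14-17 (0.401), and signalling without these 2 neuronal libraries (0.0598 and 0.0502). The median differences, mesoderm minus neuronal on the log2 scale, were 3.16 for contractile genes, 2.6 for neuronal differentiation and synapse, 1.82 for epidermis and trachea, -0.35 for identity factors, -1.19 for neuroblast genes, -0.68 for signalling, -0.72 for Polycomb and trithorax groups and -1.96 for cell cycle. Single genes singled out by the same test were CG3355 (11.36), CG32248 (10.84), TwdlJ (10.57), CG8543 (10.06), CG13040 (9.33), CG31373 (-5.37), BobA (-5.22), CG13793 (-4.91), wntD (-4.77) and CG15109 (-4.69). Several of these genes had 0 counts in a group, so the size of the fitted value depends on the prior count, and CG13040 is uncertain because other genes overlap 41.9% of its span.

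The change with stage in neuronal nuclei was unlike that in mesoderm, with a Pearson correlation across 10549 genes of 0.00328 (Spearman 0.0847), and synapse genes did not rise. The 2 neuronal libraries of stages 14-17 were the least alike of all replicate pairs (Spearman correlation 0.969, against 0.988 to 0.993 for the others). How far this weakens the neuronal stage change was not tested. If the stage labels of the neuronal libraries were exchanged, genes that fell most with stage in mesoderm could be expected to rise in neuronal nuclei; their median was -0.448, from -0.331 to -0.589 over the 4 pairings of libraries, while the 200 genes that rose most in mesoderm had a median of -0.213. Cuticle families were mixed. With stage, 16 of 19 Twdl and 34 of 54 Cpr genes fell in neuronal nuclei, while 13 of 19 and 27 of 54 rose in mesoderm. Osi genes rose in 8 of 19 cases in neuronal nuclei and in 18 of 19 in mesoderm. An exchange therefore cannot be told apart from a true difference between tissues. RNA of epidermal cells in the neuronal libraries of stages 10-13 was also weighed: the epidermis and trachea list stood 1.42 higher there than in mesoderm. This may come from such RNA or from expression in the nuclei isolated, and these cannot be told apart here either. Other sources, among them the age of the embryos, were not tested. At stages 14-17, 8 of 30 genes of the neuronal list were higher in mesoderm and 0 lower, with a median of 0.55. How pure the neuronal isolates were was not tested, and elav cannot check it because the wild-type tables miss most nested genes. A biological difference between the tissues is what the design offers, and it has no separate test in these libraries.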

How the results depend on the processing

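Every alternative setting fixed before the data were examined gave a value. Of the list results past the threshold, 376 alternative values kept direction and call and 87 lost the call, and of the named genes 3333 and 470. These totals include the settings added after seeing the data. Direction was kept by the test in all of these, although the median of the mitochondrial genome list turned to 0.01332 from -1.912 with the covariate, which is made of the same transcripts and so does not test them. Counts of genes, with the added settings included, stayed within 1.5 times of the main count in 59 cases and moved further in 27, and the cause was not tested. Leaving out 1 library gave 3794 to 4550 genes for tissue at stages 10-13, 1328 to 5647 for tissue at stages 14-17, 2862 to 3562 for stage in mesoderm, 386 to 4231 for stage in neuronal nuclei, 2000 to 5261 for the difference and 34 to 1645 for degradation. Against a 1.5-fold change the counts were 2296 (tissue, stages 14-17), 3347 (mesoderm stage), 878 (neuronal stage) and 33 (degradation). Fits of 4 libraries gave 2810 (tissue, stages 14-17) and 765 (neuronal stage), and all 14 libraries together gave 180 for degradation. For degradation DESeq2 gave 1202 genes, and the alternatives added after seeing the data gave 18 without both controls of high mitochondrial share, 0 with that share as a covariate (correlation with degradation -0.806, 3 residual degrees of freedom) and 554 without mitochondrial genes.

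The replicate block gave 5481, 4228, 4932, 2054 and 3579 genes in the wild-type comparisons in the order of the report, and 1238 for degradation. Same-numbered libraries of the degradation set had correlations of 0.22, 0.09 and 0.27 in their deviations, and each library correlated best with its own number except control replicate 2, as a hint from the data and not the design.

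In the degradation comparison, the tissue sets kept their medians but lost the call with an estimated correlation (-0.3546 and 0.1221, adjusted p = 0.339 for both). The set higher in neuronal nuclei reversed in camera's direction with sets from stages 10-13 (-0.03684), was 7.18e-06 without both high-mitochondrial controls and reversed with the covariate (0.1766, adjusted p = 0.0369). The set higher in mesoderm reversed in these added settings (-0.04128, adjusted p = 0.47, and -0.06402, adjusted p = 0.00134). With sets from stages 10-13 the set higher in mesoderm kept its direction and call. Leaving out 1 library gave -0.507 to -0.2539 for the neuronal and 0.09629 to 0.2096 for the mesoderm set. Depth may limit genes of low level, which was not tested, because the simulations kept the real library sizes. With 200 genes changed, simulated 1.5-fold changes were recovered in 13.4% of cases for degradation and 1.5% for tissue at stages 14-17. The latter share does not carry over to the real comparison, where 4340 genes passed.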

Other observations

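The explanation of neighbouring genes and that of older embryos were chosen after the result was seen, while carry-over of cytoplasmic RNA, RNA of epidermal cells and the splits of libraries had predictions written before. Gene families by name root were also counted after the lists, in 922 tests of 84 families, and 83 of these tests passed with more members than expected. The Twdl cuticle family had 11 of 23 members higher after degradation, against 0.822 expected, with a median of 0.89 (adjusted p = 6.01e-09, Fisher's exact test), and the Cpr cuticle family 6 of 56 (adjusted p = 0.0848). That test takes the members as independent, and no correlation between them was allowed for. It rests on the 557 genes called after degradation, which fell to 34 without control replicate 2 and to 0 with the mitochondrial share as a covariate. Families were not counted in those fits. Cytoplasmic ribosomal protein genes (Rp) had 0 of 84 members past the threshold after degradation, with a median of -0.67, and 79 of them stood at medians of -1.03, -0.797 and -0.0555 against control replicates 1, 2 and 3 alone. In the wild-type tables, Rp genes were lower in mesoderm than in neuronal nuclei in 65 of 82 cases at stages 10-13 and 76 of 82 at stages 14-17, and rose with stage in neuronal nuclei in 65 of 82.

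With stage in mesoderm, Osi genes rose in 18 of 19 cases and nuclear pore genes (Nup) fell in 19 of 20, with Mediator genes (MED) falling in 18 of 23 and RNA polymerase subunit genes (Polr) in 21 of 29. In neuronal nuclei, 16 of 19 Twdl, 34 of 54 Cpr and 12 of 13 Lcp cuticle genes fell with stage, while 8 of 19 Osi genes rose. Genes called higher after degradation and higher in wild-type mesoderm at stages 14-17 overlapped in 153 cases against 70.8 expected, and those called higher after degradation and higher in neuronal nuclei in 5 against 83.7. For genes called lower after degradation the overlaps were 11 against 23.5 and 46 against 27.8. The shift of the tissue sets in these directions was lost without the 2 controls of highest mitochondrial share (adjusted p = 0.48 for the neuronal and 0.47 for the mesoderm set) and reversed with that share as a covariate (0.0369 and 0.00134).

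The 9 neighbouring genes of 2L that rose after degradation were weighed against chance first: none of 10000 random gene orders held as many raised genes in 8 neighbours, giving 0.0001, the smallest p these orders can give, with 6 of 8 against at most 4. The hypothesis that Ubx represses these genes in mesoderm needs wild-type mesoderm at stages 14-17, which holds Ubx, to lie near the controls, but 8 of them stood a median of 3.95 above the controls there, from 2.26 to 4.54, and 0.0519 from the degraded libraries, from -1.41 to 1.06. Levels in these separate tables differed by -3.33 to 3.04 for 95% of 2551 genes that degradation did not change and that had at most 5.67 CPM in the controls, a range that the median and 6 of the 8 genes exceed. The 8 genes are neighbours chosen in these same data as raised from low control levels. The 2551 genes were not chosen so, and the range is therefore not a matched one. For both groups of genes, wild-type levels were scaled to library totals and degradation levels to TMM-normalised library sizes. The levels lie away from what repression by Ubx alone needs, but this comparison cannot exclude it. A genotype difference of the controls other than Ubx degradation may account for the 3.95, yet the driver and any such difference change together between the groups, so that these cannot be told apart. Earlier forms of both tests were replaced once their values were seen, and a test of vitelline membrane genes as a class was then set aside, with Vml, outside the region, at 2.22 and 2.35 CPM (0.08 ± 0.20, adjusted p = 0.845).

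After degradation 9 of 18 genes of epidermis and trachea rose (6, 0 and 11 without control replicates 1, 2 and 3, and 9, 3 and 5 without degraded replicates 1, 2 and 3, with list medians from 0.743 to 0.895) and 10 of 15 mitochondrial transcripts fell (15 without control replicate 3, 0 without any other library, with medians from -2.3 to -1.32), with neither list past the threshold at an estimated correlation (adjusted p = 0.191 and 0.400). Carry-over of cytoplasmic RNA in the controls, as the whole cause, would leave little rise against control replicate 3, whose mitochondrial share is the lowest of the controls, but the median there was 0.617, against 0.879 and 0.851 for the other controls. That control is 1 library, with a share of 1.39%, still above the 0.87 to 1.06% of the degraded libraries. Because the rise was smallest against it, a part played by carry-over is not excluded. Older embryos in the degraded libraries cannot be told apart: the 192 tested genes of those that fell most with stage in mesoderm stood at -0.0789 (0.0577 without control replicate 1, -0.194 without control replicate 3) and the 194 of those that rose most at 0.136 (0.146 to 0.205 with a library left out). The contractile list (-0.209 to -0.0693 with a library left out) and the cell cycle list (-0.05) did not move as they did between stages 10-13 and 14-17 (2.66 and -2.07), nor without the controls of highest mitochondrial share (-0.37 and 0.40) or with that share as a covariate (-0.35 and 0.59), yet a change of age within stages 14-17 was not measured. RNA of epidermal cells in the degraded libraries may contribute, since the 11 Osi genes with a mean of at least 10 CPM, which are expressed in epidermis and trachea, stood at a median of 1.01 (0.754 to 1.15 with a library left out), a value that expression in the mesodermal nuclei themselves would also give, though only 2 of the 11 passed the test (0 without control replicate 2 or degraded replicates 2 or 3, 1 without control replicate 1 and 3 without degraded replicate 1) and the whole family, with 2 of 17 and a median of 0.61, did not (adjusted p = 0.371). The 10 splits of the 6 libraries are too few for a share under 0.05: the real split gave 557 genes and the highest other 0, so that 1 of 10 splits reached 557.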
